A study of Mus musculus with 3 samples.

How the data were processed

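Total RNA of primary mouse cavernous endothelial cells, pooled over 3 numbered samples per group, was hybridised to 3 arrays of 1 slide with Cy3 labelling, per the labels' protocols. The arrays were read in a single scan. Per the file headers, spot intensity was extracted with Agilent Feature Extraction 11.0.1.1, which subtracted background to give a processed signal on a linear scale. The files carry 43020 non-control spots for 39429 probes, of which 399 are printed 10 times. The series value table deposited by the authors holds linear intensity as well: each column equalled its own array's processed signal to within 0.1% for 100% of the 39030 probes with a single spot. The column medians were 118 for normal glucose, 118 for high glucose and 129 for high glucose with siRNA, so its scale is linear without centring, and how repeated spots were combined stayed unknown.

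Arrays were assigned to groups by the labels. The file names carry group words that exchange the 2 high-glucose arrays, and slide positions inside the files (2 for normal glucose, 3 for high glucose, 1 for siRNA by label) differ from those in the file names (1, 3 and 2). The value table could not settle this, because its columns follow the same assignment as the files. All arrays share the slide and the scan, so no batch term was available.

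Spots marked as outliers were left out, 109, 147 and 107 on the arrays labelled normal glucose, high glucose and siRNA. The log2 of the processed signal was averaged over the spots of a probe and each array's 75th percentile over non-control probes was subtracted. A probe counted as well above background where that mark of the scanner software held for at least 50% of its spots. Where 1 of 2 arrays was not well above background, the difference is a bound: the bright value against the higher of the dim probe's own value and the lowest value well above background on the dim array. The precision is limited by the number of arrays, 1 per group. Spots of the 300 repeated probes above background on every array had a median SD of 0.06 on the log2 scale, which gives 0.08 for a difference of 2 spots. This covers spot noise only, with no cell culture or hybridisation error.

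Probes were named by matching their accession without version to the RefSeq gene table of GRCm38.p6. The files were annotated on mm9, so no coordinates are given. In all 26055 of 39429 probes (66.1%) were named, for 19751 genes, and 13374 probes were left out of the gene comparisons. Each gene was represented by its brightest probe above background on at least 1 array. Lists of genes were fixed before the data were examined (33 lists, 695 entries, all found in the table). Each list's median was placed among 10000 random lists of the same size drawn from 20 brightness groups, as a description of these arrays. Genes were named by a rule fixed at the same time: the 12 largest measured differences of at least 2-fold in each direction whose other probes moved the same way, the 4 largest bounds in each direction, up to 4 members per list, the 5 largest each way for the siRNA label against normal glucose, the 8 most opposed genes, and a set of angiogenic, neurotrophic and nitric oxide genes that includes Ninj1, Ninj2, Angpt1, Angpt2, Tek, Vegfa, Bdnf, Ntf3, Nos1 and Nos3. Symbols of unnamed gene models were passed over. Only part of the genes that this rule names are printed. No p-value is given, since genes are not replicates.

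For the shared array, 3 arrays with no effect were simulated. Spot noise was gauged from pairs of spots of a repeated probe on the same array, with and without the spots marked as outliers of their probe's population, because that mark can only fall on repeated probes. The version that keeps them was added after the other had been seen. The steps were tested on simulated arrays made from the levels and spot noise of the array labelled normal glucose (14749 genes, high glucose against normal glucose). Of 50 genes changed by 2.5-fold 49 passed 2-fold, as did 50 of 50 changed by 4-fold, 47 of 47 changed by 8-fold and 0 of 48 changed by 1.5-fold, with 55 of 14549 unchanged genes past 2-fold. Of 200 unchanged lists of 20 genes 4% fell outside the central 95% of random lists, and 100% of those shifted by 0.5 did. These lists were drawn at random, so they do not cover lists whose genes vary together.

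Alternatives were quantile normalization, cyclic loess, scaling to the median of probes above background on every array, normexp background correction with an offset of 50, the series value table, no filter on dim probes, a filter on every array, the mean over a gene's probes, thresholds of 1.5-fold and 3-fold, and an exchange of the 2 high-glucose arrays. Normexp was planned on mean spot signals, which the files used here do not carry, and was run on median spot and median background signals. Assignment by slide position, a filter on bright genes and support from a second probe were added after the data were seen. Leaving out a replicate was not possible with 1 array per group. Computations used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.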

Results

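Mouse cavernous endothelial cells, primary cells grown from the erectile tissue of C57BL/6 mice, were profiled on 3 single-colour expression arrays to ask how high glucose alters gene expression and how an siRNA against Ninj1 alters that response. Ninj1 encodes ninjurin 1, a cell-surface adhesion protein first described after nerve injury. The labels assign 1 array to normal glucose (5 mmol), 1 to high glucose (30 mmol) and 1 to high glucose (30 mmol) with the siRNA (200 pmol), each after 48 h and each from RNA pooled over 3 numbered samples. The labels do not say whether cells without the Ninj1 siRNA received a control siRNA. The cells are called endothelial by the labels. The endothelial identity list had an unscaled median signal of 158, 163 and 279 on the arrays labelled normal glucose, high glucose and siRNA. For the fibroblast list it was 21091, 21169 and 13706. The unscaled medians do not give the direction gene by gene. After scaling, 11 endothelial genes were higher and 15 lower under the siRNA label than under the high-glucose label, with a median log2 difference of -0.21. Probes differ in brightness, so these signals give no share of cell types, and the differences below cannot be assigned to endothelial cells. Of 39429 probes, 67.0% were well above background on the array labelled normal glucose, 67.6% on the array labelled high glucose and 70.6% on the array labelled siRNA, and no spot was saturated. Expression could be compared for 15764 named genes that were above background on at least 1 array. With 1 array of pooled RNA per group no difference has a replicate check and no test was run, so "higher" and "lower" describe these arrays only.

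The siRNA's target went against the labels. Ninj1 gave a signal of 20413 on the array labelled normal glucose, 16291 on the array labelled high glucose and 25539 on the array labelled high glucose with Ninj1 siRNA, so the unscaled target signal was highest where the label places its siRNA. All Ninj1 values rest on 1 named probe with 1 spot per array. After scaling, Ninj1 was 1.34-fold higher on the array labelled siRNA than on the array labelled high glucose (log2 difference 0.42) and 1.22-fold lower on the array labelled high glucose than on the array labelled normal glucose (-0.28). Spots of one probe on one array differed by a typical 0.08 on the log2 scale. The Ninj1 difference of 0.14 between the arrays labelled siRNA and normal glucose was 0.08 with quantile normalization and 0.04 with cyclic loess, both under that spread, so these arrays are not told apart by Ninj1 under every scaling. Between the arrays labelled high glucose and normal glucose, the Ninj1 difference lay at percentile 0.0562 among equally bright genes. The differences of the array labelled siRNA from those labelled high glucose and normal glucose lay at percentiles 82.6 and 64.4. A percentile only ranks Ninj1 among the differences of other genes and gives no error for Ninj1. Across probes, differences had an SD of 0.21 between the high-glucose and normal-glucose labels, and 0.71 between the siRNA and high-glucose labels. The group words in the names of the deposited files place the 2 high-glucose arrays the other way round, and the slide positions recorded inside the files differ from those in the file names for all but 1 array. Groups are therefore called by their labels throughout, and each direction below holds for the array so labelled, not for a verified treatment.

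Among the angiogenic and neurotrophic genes named in advance, the array labelled siRNA differed from the array labelled high glucose in both directions. Vegfa, the main endothelial growth factor, was 2.09-fold higher on its brighter probe and 2.07-fold higher on its other probe, and Angpt2, an antagonist of the Tie2 receptor, was 1.56-fold higher. Angpt1, the activating ligand of Tie2, was 2.35-fold lower, Ntf3, encoding neurotrophin 3, was 2.15-fold lower, and Tek, the gene of Tie2 itself, was at least 3.81-fold lower, being not well above background on the array labelled siRNA. Tek was dim on the other arrays too, with a signal of 41.2 under the normal-glucose label and 38.1 under the high-glucose label, from 1 spot each. Bdnf, encoding brain-derived neurotrophic factor, and Nos3, encoding endothelial nitric oxide synthase, differed by 1.04-fold and 1.09-fold, Ninj2 was 1.43-fold higher, and Nos1 was not well above background on any array. Between the arrays labelled high glucose and normal glucose, the largest difference in this set apart from Ninj1 was that of Ninj2, which was 1.13-fold lower under the high-glucose label.

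**Figure D1:**
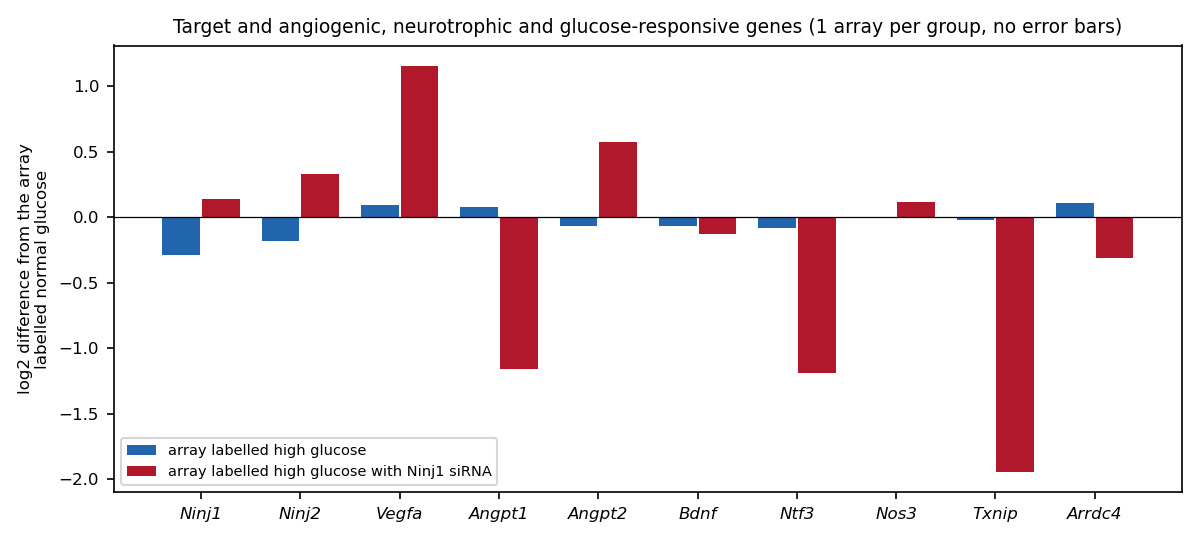
Log2 difference of each gene from the array labelled normal glucose, for the arrays labelled high glucose (blue) and high glucose with Ninj1 siRNA (red); each bar is 1 probe on 1 array, so there are no error bars. Ninj1 lies at -0.28 on the array labelled high glucose and at 0.14 on the array labelled siRNA, while Vegfa reaches 1.16 and Txnip -1.94 on the array labelled siRNA.

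The arrays labelled high glucose and normal glucose were nearly alike. Over 25539 probes well above background on every array their levels correlated at r = 0.998 across probes, and of 15081 genes compared 123 were at least 2-fold higher and 104 at least 2-fold lower under the high-glucose label. Only 40 and 28 of these were measured on both arrays, and the others are bounds with 1 array not well above background. The highest measured genes were Nyx, encoding the retinal proteoglycan nyctalopin (17.0-fold), and Slc18a1, a vesicular monoamine transporter (13.3-fold). They were followed by Cracdl (7.50-fold), Dppa3, a maternal chromatin factor of the early embryo (7.13-fold), Cyp4a12b, a cytochrome P450 (6.81-fold), Csmd1 (6.77-fold), Sez6l (6.67-fold), Npat, a regulator of histone transcription (6.12-fold), Mboat4, the ghrelin acyltransferase (5.67-fold), the neural adhesion genes L1cam (5.28-fold) and Cntn2 (5.16-fold), and Scn11a, a sodium channel of sensory neurons (4.79-fold).

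The lowest measured genes under the high-glucose label were Olfr458, an olfactory receptor (12.5-fold), Acr, the sperm protease acrosin (11.3-fold), Prph2, a photoreceptor protein (7.50-fold), Hba-a2 and Hba-a1, near-identical alpha-globin genes whose probes may share signal (5.68-fold and 5.31-fold), and Frmpd4 (5.64-fold). Pudp (5.26-fold), Sec22a (4.13-fold), Ptpro (4.06-fold), Zcwpw1 (4.03-fold), Ccl28 (4.03-fold) and Fam81a (3.78-fold) completed the set. The largest bounds were at least 43.1-fold for Olfr95, 30.7-fold for Olfr1450, 16.5-fold for Gad1 and 14.1-fold for Tas2r104 on the higher side, and at least 24.4-fold for Ctla4, 24.2-fold for Calml3, 18.4-fold for Jpx and 15.7-fold for Olfr1321 on the lower side. Each of the 227 genes past 2-fold rested on a single spot per array, where 4.03 would be expected among the 268 genes read by 10 spots. Of the 68 measured ones, 29 lay in the dimmest brightness group and 35 in the next. With normexp background correction the counts were 43 and 33, with only probes above background on every array 35 and 26, and with no filter on dim probes 434 and 330.

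Gene groups fixed in advance moved little between these arrays: the largest median over 33 lists was 0.14 in size on the log2 scale. Interferon-stimulated genes had a median difference of 0.06 (percentile 100 among 10000 random lists of equally bright genes), with Cmpk2, a mitochondrial nucleotide kinase, at 0.42. Hypoxia targets stood at 0.05 (percentile 99.9) and glycolysis genes, of which 6 are also in the hypoxia list, at 0.04 (percentile 99.7). Osmotic stress targets stood at -0.11 (percentile 0.1), with the betaine transporter Slc6a12 at -0.22, and cholesterol synthesis genes at -0.07 (percentile 0.3), with squalene epoxidase, Sqle, at -0.23. Smooth muscle markers (-0.08, percentile 1.08), epithelial markers (-0.14, percentile 1.65, 5 genes) and fibroblast markers (0.02, percentile 97.7) also lay outside the central 95% of random lists, which makes 8 lists. If genes varied independently, 1.65 would lie outside, but genes of a list may vary together, so this is no chance rate for these lists. Txnip, the thioredoxin-interacting protein gene that glucose induces in many cell types, differed by -0.02.

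The array labelled high glucose with Ninj1 siRNA stood apart from the array labelled high glucose. Of 15624 genes compared, 1018 were at least 2-fold higher and 1283 at least 2-fold lower, 876 and 1043 of them measured on both arrays, and with normexp background correction the counts were 620 and 783. Among the genes named by the rule fixed in advance and measured on both arrays, the largest differences were those of Csta3 and Il11 on the higher side and of Ogn and Lgr5 on the lower side. Where a second probe could be read, it moved the same way for 367 of 383 genes past 2-fold and was itself past 2-fold for 245. These directions follow labels that Ninj1 went against.

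Among the largest higher values, Il11, an interleukin-6 family cytokine, was 20.9-fold higher, the alarmin Il33 11.2-fold, the epidermal growth factor receptor ligand Areg higher by 3.46 on the log2 scale, and Selp, the endothelial adhesion molecule P-selectin, 9.96-fold. The named genes include 4 of the stefin A family, inhibitors of cysteine proteases: Csta3 was 21.1-fold higher, Cstdc4 12.5-fold, Csta2 12.1-fold over 10 spots and Cstdc5 10.3-fold, although these are close paralogs whose probes may share signal. Lce3a, a gene of the cornified envelope, was 13.6-fold higher, the transcriptional coregulator Cited1 12.3-fold, the keratin Krt23 11.3-fold and Atp13a4, a P-type transport ATPase, 10.1-fold. The largest bounds on this side were at least 13.6-fold for Ppp1r17, 9.57-fold for the homeobox gene Hoxa4, 9.35-fold for Olfr850 and 8.76-fold for Olfr1020.

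On the lower side, Ogn, encoding the matrix proteoglycan osteoglycin, was 123-fold lower, from a signal of 25444 on the array labelled high glucose to 241 on the array labelled siRNA. Lgr5, the R-spondin receptor and stem cell marker, was 57.2-fold lower, the interferon-induced genes Ifitm1 and Ifi27l2a 49.1-fold and 28.1-fold, Ecrg4 30.7-fold, the collagen-binding integrin Itga11 29.5-fold, and Fndc1 25.6-fold with its second probe in the same direction. Ggt5, a gamma-glutamyltransferase that acts on leukotriene C4, was 23.6-fold lower, Ms4a4d 21.3-fold and the Wnt modulator Sfrp2 19.1-fold. Olfr95 and Nyx, 24.9-fold and 18.9-fold lower, were also among the highest under the high-glucose label above. The largest bounds were at least 68.4-fold for Omd, encoding osteomodulin, 43.7-fold for Olfr1450, 30.5-fold for Dppa3 and 30.5-fold for the matricellular gene Ccn5. Olfr1450 and Dppa3 were likewise among the highest under the high-glucose label. Their signals were 503 and 305 there, against 3.66 and 44.0 on the array labelled normal glucose.

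**Figure D2:**
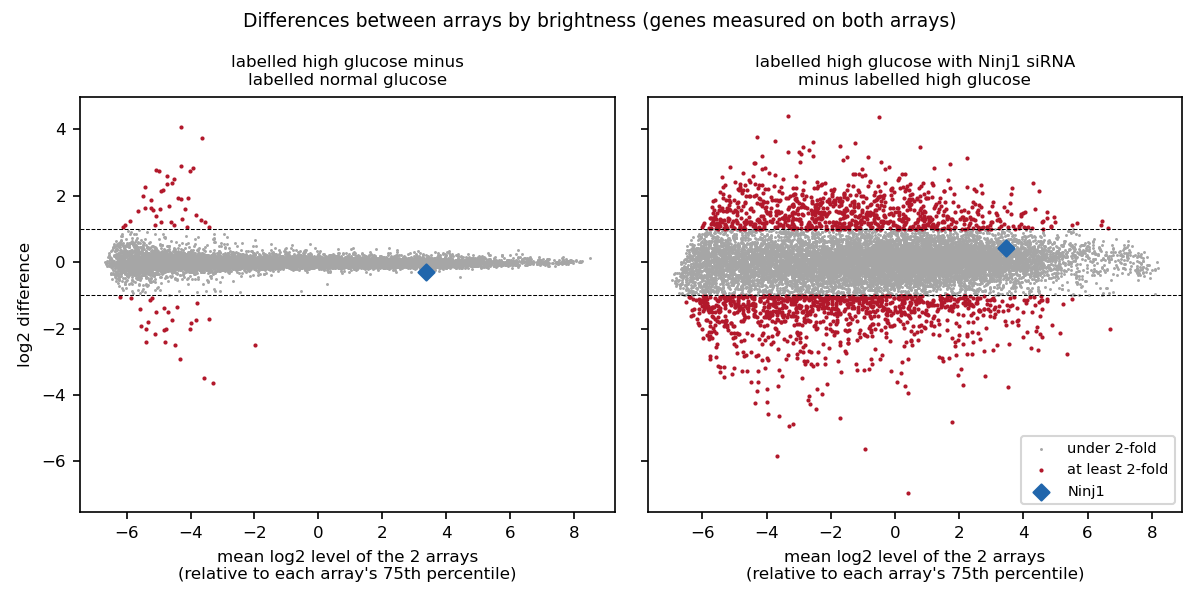
Log2 difference between 2 arrays (vertical) against the mean log2 level of both, relative to each array's 75th percentile (horizontal), for the genes measured on both arrays; red points are at least 2-fold different, dashed lines mark 2-fold and the blue diamond is Ninj1. The 68 red points on the left lie at the dim end, whereas the red points on the right (876 higher, 1043 lower) spread over the brightness range.

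Cell cycle genes were the group that differed most between the arrays labelled siRNA and high glucose. Their median was 3.09-fold higher under the siRNA label (percentile 100 among 10000 random lists of equally bright genes), and 29 of 32 were at least 2-fold higher with none at least 2-fold lower. The replication licensing genes Mcm5 and Mcm3 were 5.26-fold and 4.85-fold higher, the topoisomerase Top2a 4.90-fold and the transcription factor Mybl2 4.81-fold. Genes of cell adhesion and junctions had a median of 0.33 (percentile 99.5) with the endothelial cadherin Cdh5 2.86-fold higher and the cytoskeletal linker Vcl 2.31-fold lower, those of the unfolded protein response 0.31 (percentile 99.8) with Atf3 2.28-fold higher, and hypoxia targets 0.28 (percentile 98.0) with Adm, encoding adrenomedullin, 3.38-fold lower against that direction.

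Interferon-stimulated genes were lower together under the siRNA label, by a median of 2.03-fold (percentile 0), with 15 of 28 at least 2-fold lower and none at least 2-fold higher. The antiviral genes Oas2 and Ifit3 were 5.19-fold and 4.30-fold lower and the viral tether Bst2 3.88-fold. All 22 cholesterol synthesis and uptake genes were lower, by a median of 1.83-fold (percentile 0). They included the isomerase Idi1 at 2.99-fold and the mevalonate pathway kinase Pmvk at 2.41-fold. Inflammatory activation genes went both ways around a median of -0.35 (percentile 0.07), with 5 at least 2-fold higher, such as the cytokine genes Csf3 at 4.90-fold and Il6 at 4.74-fold, and 5 at least 2-fold lower, such as the chemokine Cxcl5 at 6.83-fold.

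Matrix and stromal groups were lower on the array labelled siRNA, apart from matrix metalloproteinases and their inhibitors (median -0.008, percentile 36.6). The median of 18 fibroblast markers was 1.67-fold lower (percentile 0), with 7 at least 2-fold lower: Dpt, encoding dermatopontin, by 8.46-fold, the proteoglycan Lum by 6.79-fold, Fbln1 by 4.57-fold and the collagen Col3a1 by 3.74-fold. The matrix and TGF-beta list, which shares 3 genes with it, had a median of -0.56 (percentile 0), with Ccn2, a TGF-beta target, 7.46-fold lower and smooth muscle actin, Acta2, 5.02-fold lower against a 3.80-fold higher Tnc, encoding tenascin C. Smooth muscle and pericyte markers had a median of -0.46 (percentile 0.42), with Pdgfrb, the platelet-derived growth factor receptor of pericytes, 2.88-fold lower. Anti-angiogenic factors stood at -0.50 (percentile 0), with the metalloproteinase inhibitor Timp3 9.37-fold and thrombospondin 1, Thbs1, 4.38-fold lower.

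Oxidant and osmotic groups completed the 13 lists outside the central 95% of random lists, where 1.65 would lie outside if genes varied independently. NADPH oxidase and pro-oxidant genes had a median of -0.61 (percentile 0.21), with the phagocyte oxidase subunit Cybb 4.55-fold lower and Txnip 3.79-fold lower, by 3.50-fold on its second probe. Cybb was dim, with a signal of 63.3 under the high-glucose label and 16.3 under the siRNA label. Osmotic stress targets had a median of -0.59 (percentile 0.15) over 9 genes, of which the water channel Aqp1 was 3.12-fold lower and Slc6a12 2.54-fold higher. The medians of the other 20 lists lay between -0.21 and 0.52. Endothelial identity genes were the lowest of these, with Sox7 and Cdh5 3.05-fold and 2.86-fold higher and Vwf, encoding von Willebrand factor, 2.40-fold lower. Vwf was dim as well, at 66.2 under the high-glucose label and 32.3 under the siRNA label. In the angiogenic list, whose median was -0.09, Igf1 was 9.87-fold lower on a gene with 3 further probes in the same direction, Vegfd 5.68-fold and Vegfc 5.08-fold lower, and Esm1, a marker of endothelial tip cells, 4.43-fold higher.

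**Figure D3:**
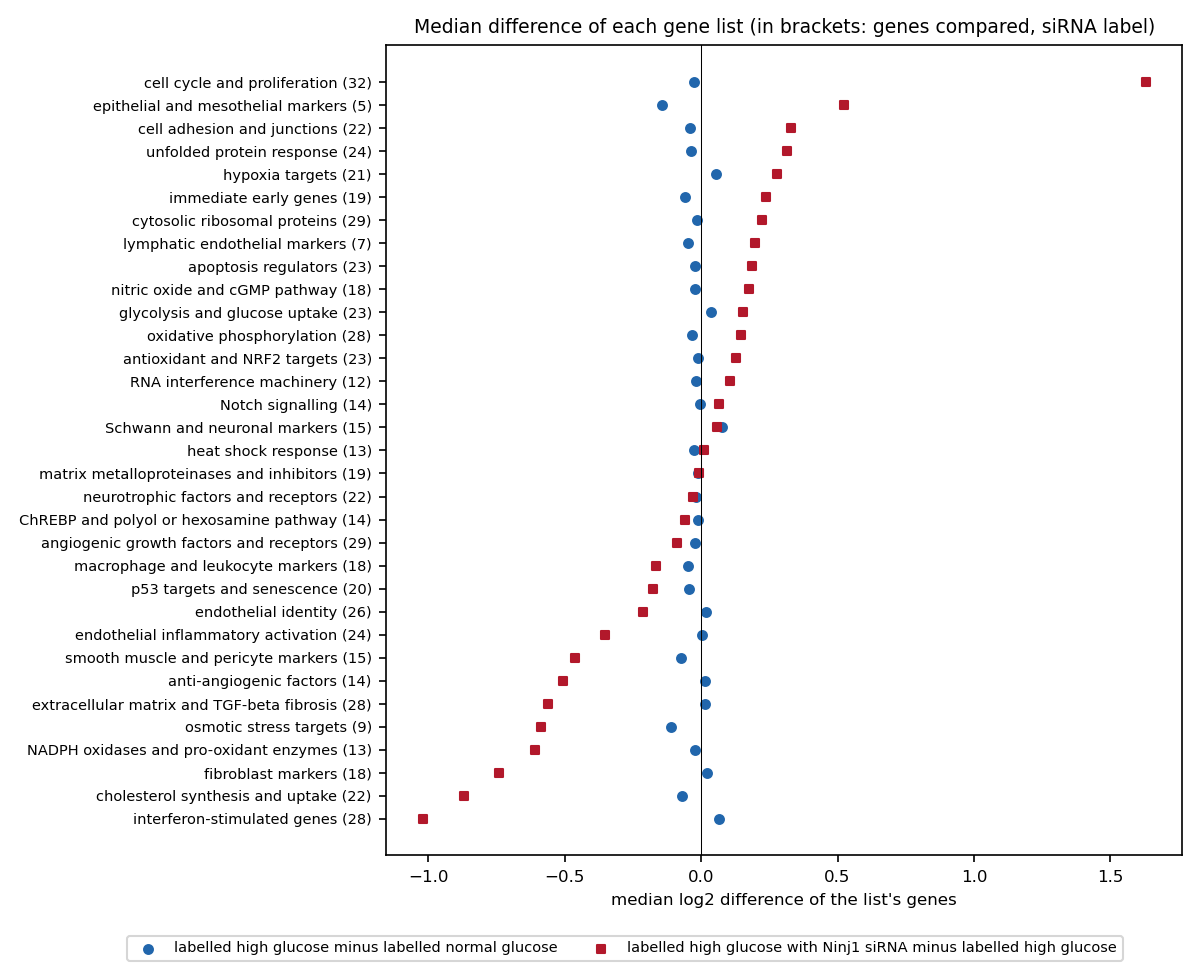
Median log2 difference of the genes in each of 33 lists (horizontal axis), for the array labelled high glucose minus that labelled normal glucose (blue circles) and the array labelled high glucose with Ninj1 siRNA minus that labelled high glucose (red squares); numbers in brackets count the genes compared under the siRNA label. Blue circles stay within 0.14 of 0, and red squares run from -1.02 for interferon-stimulated genes to 1.63 for cell cycle genes.

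Set against the array labelled normal glucose, the array labelled siRNA showed nearly the same profile: 990 genes were at least 2-fold higher and 1236 at least 2-fold lower, or 605 and 770 with normexp. Il11 was 19.5-fold higher, Areg 12.5-fold, Il33 12.2-fold, Cstdc4 12.1-fold and Csta3 11.9-fold. Ogn was 120-fold lower, Lgr5 56.7-fold, Ifitm1 46.6-fold, Itga11 32.7-fold and Ifi27l2a 28.2-fold. In both comparisons 915 genes were at least 2-fold higher and 1006 at least 2-fold lower. Independent lists would share 65.3 and 84.4, but these lists are not independent. Both comparisons hold the array labelled siRNA, and the other 2 arrays were nearly alike (r = 0.998). The differences correlated at r = 0.957 across genes, beside 0.491 simulated for no effect with a shared array and equal spread, which is unlike these arrays. The overlap follows from this design and adds no separate support.

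Whether the siRNA label opposed the high-glucose difference was asked of the genes that differed by at least 2-fold between the arrays labelled high glucose and normal glucose. Of 163 such genes that could be read in both comparisons, 143 had the opposite sign under the siRNA label (87.7%), and 118 were opposed by at least 2-fold with 2 moving the same way. The count of opposed genes was 42 with normexp, 32 with only probes above background on every array and 359 with no filter on dim probes. Among genes measured on both arrays of each comparison, those most opposed by the smaller of their differences were Nyx, Slc18a1, Csmd1, Sez6l, Npat, Cyp4a12b, Mboat4 and L1cam, higher by 17.0-fold to 5.28-fold under the high-glucose label and lower by 18.9-fold to 5.73-fold under the siRNA label. Both differences hold the array labelled high glucose, so opposite signs arise without an effect. Arrays simulated with no effect gave opposite signs in 94.8%, above the 87.7% seen. Those arrays had equal spread, whereas across probes the difference of the siRNA label from the high-glucose label had an SD of 0.71. Between the high-glucose and normal-glucose labels it was 0.21. The simulation therefore cannot say what share or correlation would arise here without an effect. Across 14944 genes the differences correlated at r = -0.32 with a covariance of -0.07, beside -0.50 and -0.04 simulated for no effect, and with different probes of a gene for each difference the correlation across 3700 genes was -0.05.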

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

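Control spots that take no part in the comparisons had a median signal above that of the negative controls. The median signal of 36 spots of 1 control family was 13.7 on the array labelled normal glucose, 13.6 on the array labelled high glucose and 14.1 on the array labelled siRNA, beside 4.04, 3.80 and 3.18 for 153 negative control spots. Of these 36 spots, 38.9%, 47.2% and 52.8% were well above background on the 3 arrays in that order, so on the first 2 most were not.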

How the results depend on the processing

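With the 2 high-glucose arrays exchanged, the Ninj1 differences became 0.14 for high glucose against normal glucose, -0.42 for siRNA against high glucose and -0.28 for siRNA against normal glucose, genes at least 2-fold higher and lower under high glucose 990 and 1236, those under siRNA against normal glucose 123 and 104, and opposed genes 1921. With arrays assigned by slide position, an alternative chosen after seeing the data, the Ninj1 differences were -0.14, -0.28 and -0.42, and the counts 1236 and 990 for high glucose against normal glucose and 123 and 104 for siRNA against high glucose. By their construction these alternatives only rename the arrays.

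The other values keep the labels. Counts of genes higher and lower are given in order for high glucose against normal glucose, siRNA against high glucose and siRNA against normal glucose, beside 123 and 104, 1018 and 1283, and 990 and 1236. Normexp gave 43 and 33, 620 and 783, and 605 and 770, with 42 opposed genes in place of 118; the cause was not tested. At 1.5-fold the counts were 229 and 187, 2236 and 2460, and 2148 and 2405, and at 3-fold 409 and 524 and 393 and 508 in the comparisons with siRNA. Without a filter on dim probes the first comparison gave 434 and 330, with 359 opposed genes, and with only probes above background on every array 35 and 26, with 32 opposed genes. Among genes brighter than the median, chosen after seeing the data, the counts were 0 and 0, 306 and 402, and 277 and 401. Where each of 2 or more probes had to pass, also chosen later, they were 0 and 0, 108 and 128, and 106 and 121, from fewer genes. Under cyclic loess Ninj1 differed by 0.32 between the siRNA and high-glucose labels and by 0.0422 between the siRNA and normal-glucose labels.

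Of 792 list medians under these settings 744 moved from their main value by less than the SD of the random lists' medians, and none that lay outside the central 95% changed sign. Of 2891 values of named genes and the correlation of differences 2559 moved by less than the spot spread or, for the correlation, 0.1, and none past 2-fold changed sign. The other 332 moved by more, and 174 of them were among the 364 values under normexp, so folds of named genes depend on that setting. It changed the background correction, the offset and the spot signal together, and which of these moved the values was not tested. No paired analysis was possible because each group has 1 array. Signal over background limits the first comparison to bounds for 83 of its 123 higher and 76 of its 104 lower genes.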

Other observations

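Probes without a gene name also differed more often under the siRNA label. Of 8242 such probes above background on at least 1 array, 1070 differed by at least 2-fold between the arrays labelled siRNA and high glucose. Between the arrays labelled high glucose and normal glucose 289 did. These are 13.2% and 3.83% of the probes that could be compared in each case, beside 14.7% and 1.51% of the named genes. In other lists, Hmox1, the heme oxygenase of the oxidative stress response, was 4.68-fold higher under the siRNA label, the glutathione transferase Gstm1 3.48-fold lower, the Notch target Hes1 4.28-fold higher, the Notch ligand Jag2 2.93-fold higher, and the immediate early gene Nr4a1 4.99-fold higher. The cytokine gene Lif was 3.87-fold higher and its receptor gene Lifr 5.17-fold lower, with its 2 other probes in the same direction. The matrix protease Adamts5 was 15.6-fold lower and Mmp10 4.61-fold higher, and the death receptor gene Fas was 4.62-fold lower.

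In this part, the tests of Ninj1 under the deposited labels, of its percentile for the slide position, of the share of fibroblast-like cells and of spot pairs on one array were chosen only after the results or values that bear on them were seen, as was the look at Txnip. Ninj1 was not lowest on the array labelled with its siRNA: its difference from the array labelled high glucose was 0.42. That is opposite in sign to an effective knockdown under the labels as deposited, and beyond the 0.08 spread between spots. By the bound written afterwards it speaks against such a knockdown, but spot noise leaves out culture and hybridisation error, with 1 array per group. A later rule left it undecided at percentile 82.6 among equally bright genes. That percentile only ranks Ninj1 among the differences of other genes, so it cannot decide. An exchange of the 2 high-glucose arrays, as the file names have it, or an assignment by the slide position inside the files, may account for the sign of the Ninj1 difference. Both place the siRNA on the array labelled high glucose. By slide position the knockdown would be that array against the array labelled normal glucose, where Ninj1 lay at percentile 0.0562, and by exchange it would be that array against the array labelled siRNA, where the difference is the 0.42 above with its sign turned. These readings cannot be told apart here: Arrdc4, a gene that glucose induces, stood at -0.31 on the array labelled siRNA relative to normal glucose on its 10-spot probe, which by the bound set beforehand would speak against the exchange, but at 0.40 on its other probe, and the rule that leaves such a split undecided was added afterwards. Txnip was lower there on both probes (-1.94 and -1.91), which would favour slide position over exchange if glucose induces Txnip in these cells, and that was not tested. On the same premise Txnip would not favour the labels as deposited. Its 2 probes stood at -0.02 and -0.10 on the array labelled high glucose relative to normal glucose.

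The array labelled siRNA stood apart from the other 2 arrays. The tables argue against a difference in scale or brightness response, since 2279 genes still differed by at least 2-fold from the array labelled high glucose under cyclic loess. A lower share of fibroblast-like cells as the whole cause was taken to raise markers of the other cell types alike. The medians of those lists spread over 0.99, from -0.46 for smooth muscle and pericyte markers to 0.52 for epithelial and mesothelial markers. This gap passed the bound written afterwards, 2 times the larger SD among random lists (0.34), and so counts against that whole cause. The outcome is weak, because its upper end rests on 5 genes. At its lower end, Acta2 is also in the matrix and TGF-beta list. Within the fibroblast list 14 genes were lower and 4 higher. Macrophage and leukocyte markers went both ways, with 4 genes at least 2-fold higher and 5 at least 2-fold lower. A lower share of fibroblast-like cells therefore stays open as part of the cause, and is only weakly argued against as the whole. An effect of glucose, an effect of the siRNA and a difference between cultures stay open and untested, since each group is 1 pool and the labels are in doubt.

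Genes at least 2-fold different between the arrays labelled high glucose and normal glucose were dimmer than most: 100% had a brighter level under the median of the genes compared. That bound, set before the value was seen, is weaker than lying near background: of 68 measured genes 29 and 35 lay in the 2 dimmest brightness groups, but the brighter signal of Hba-a2 was 1074. Noise of single spots may account for part of them but stays undecided: pairs of spots of one probe on one array predict 51.3 genes, beside 68 measured ones, when spots marked as outliers of their probe's population are kept, and only 4.11 when they are left out, which was the version run first. The correlation between 2 probes of a gene was 0.11 across genes, but only 2 of the genes past 2-fold had a second probe, and the rule that leaves so few undecided was also added afterwards. These arrays differed beyond spot noise, with 45% of the 300 repeated probes beyond 2 SE of their spots, which hybridisation alone could give, so a small real difference stays open.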
